A study of Arabidopsis thaliana with 18 samples.

How the data were processed

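RNA was measured in 18 libraries of Arabidopsis thaliana seedlings grown in liquid medium. Wild type (accession Col-4) and nlp2-2, a T-DNA insertion knock-out of the gene NLP2, were each sampled untreated at 10 days, after 3 days without nitrogen at 13 days, and after 3 mM nitrate was given back to starved seedlings for a time labelled 30, whose unit is not given in the sources used here. Each of the 6 groups holds 3 libraries, which the series design calls biological replicates. Libraries were poly(A)-selected, stranded and read from 1 end, per the labels' protocols. Age and starvation change together, so comparisons of starved with untreated seedlings cannot separate them. No starved group without nitrate was sampled at the time labelled 30. Comparisons of nitrate with starvation therefore cannot separate nitrate from handling or elapsed time.

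The values used are counts of reads per gene model, which the authors deposited as whole numbers for 33602 gene models in each library. The counts were made with sam2pkm after reads with equally good hits elsewhere had been removed, per the file headers, a step that took 1.9% to 2.17% of the mapped reads of each library. Reads were aligned with Bowtie2 to TAIR10, per the submitters' processing notes. The versions, the annotation and the use of strand in counting are not given in the sources used here. The column sum equalled the total in the header in all 18 libraries. Between 14684639 and 25545031 reads were counted per library, 96.97% to 98.53% of reads were mapped, and 23347 to 23999 gene models had a read. Removal of reads with equal hits lowers the counts of near-identical copies, such as NRT2.1 and NRT2.2, the RBCS genes and the LHCB1 genes, so their values are uncertain. Without a statement on strand, reads of overlapping genes on opposite strands, such as MRD1 and HEI10, cannot be told apart. No pair of libraries within a group differed by as little as sampling noise.

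Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (count minimum 10, total minimum 15), which left 21347 genes. Counts were scaled with TMM, and a robust quasi-likelihood model with 1 mean for each of the 6 groups was fitted to all 18 libraries, which left 12 residual degrees of freedom. The common biological coefficient of variation was 0.129. Genes were called at an adjusted p below 0.05 (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjustment within each comparison), and ± after a log2 fold change is its standard error. Levels are counts per 1e+06 (CPM) on TMM-scaled library sizes, as mean ± SD over 3 libraries. The comparisons were nlp2 against wild type in each condition, nitrate against starvation and starvation against no treatment in each genotype, and the difference between the genotypes in each of these responses. A positive difference is a larger value in nlp2. For the size of the induction response, genes were taken that rose or fell with nitrate on average over both genotypes.

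Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of the 24 lists, all but that of cytosolic ribosomal proteins together hold 352 members. Of these, 331 carry the listed symbol in the reference annotation (TAIR10.1), 13 have no symbol there and 8 have another symbol for the same identifier. The ribosomal list holds 28 genes found by name in that annotation. The lists are nitrate transport, nitrate and ammonium assimilation, primary nitrate response regulators, the NLP family, reductant supply, organic acid metabolism, transport of ammonium, urea and amino acids, systemic nitrogen demand, flavonoid and anthocyanin synthesis, photosynthesis, cytokinin, senescence, autophagy, phosphate starvation, sulfate assimilation, iron, starch and sugar, cell cycle, touch with wounding and jasmonate, hypoxia, the circadian clock, root tissue markers, cytosolic ribosomal proteins and seed storage markers. Of these, 23 were tested, since no seed storage gene passed the filter. Lists were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 23 lists of a comparison, and again with an estimated correlation. For each list that the report names as called over all 18 libraries it gives the number of members called over all genes tested and adjusted over the list alone. Where a list was called, its median, mean and test had the same sign. Another 2 lists, heat-shock genes and salicylic acid defence genes, were chosen after the data were seen, and their camera p-values were adjusted over the 18 tests of both lists. Those of the genes that rose or fell with nitrate were adjusted over these 2 sets.

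The genes named in the text are the NLP family; the 6 called genes with the largest fold change in each direction, among those with a symbol, a mean of at least 5 CPM in a group and no overlap between groups; up to 4 called members of each list with the smallest p; a panel of 13 nitrate response genes in the induction comparisons; up to 10 genes called in all 3 genotype comparisons; and genes within 3 models of NLP2. Uncalled members were named only from the lists on nitrate transport, assimilation, regulators and reductant supply. Genes named outside this rule are said to be chosen after their values were seen. Of the 33602 gene models counted, 32835 are in the reference, and 10654 have a symbol there. Coordinates are those of TAIR10.1, counted from 1.

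Replicate numbers come from the labels. Replicates 1, 2 and 3 were planted in February, October and November in the 13 libraries whose labels give a planting month; the 5 others, starved wild type and replicates 1 and 2 of wild type after nitrate, have none. The numbers paired the genotypes within each condition: deviations from the group means correlated at 0.41 to 0.554 before starvation, at 0.267 to 0.343 after starvation and at 0.201 to 0.487 after nitrate, over 3 pairs each. They also paired nlp2 before and after starvation (0.187 to 0.32). In the other response comparisons at least 1 pair was at or below 0.1. With the replicate number as a block, 143, 137 and 360 genes were called in the genotype comparisons.

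The fit was tested on simulated counts of 21255 genes with 200 genes changed. Changed genes had a mean of at least 5 CPM, and libraries were drawn independently, without the replicate signal of the real data. The shares found hold for such genes and libraries only. For nlp2 against wild type after nitrate, 64.2% of genes changed 1.5-fold were recovered, 92.5% of those changed 2-fold and 100% of those changed 4-fold. For the difference of the induction response the shares were 11.9%, 80.6% and 100%. Unchanged genes called numbered 2 before starvation, 10 after nitrate and 8 for the difference. Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter of 1 CPM in 9 libraries, the replicate block, a fit to the compared groups only, a test against a 1.5-fold change, an estimated inter-gene correlation, windows of 2 and 10 Mb, and leaving out each library in turn. Leaving out the replicate 1 libraries after nitrate of both genotypes was added after the data were seen. A ratio against a group with no reads is a lower bound, computed at a floor of 3 counts over the group, and a ratio against 1 to 3 counts has a 95% counting interval. Intervals and floors cover counting error only. Tables were prepared in Python 3.11.15 with pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Isoforms, single-base variants and the insertion itself were not analysed here.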

Results

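Transcript levels were measured by RNA sequencing in seedlings of wild type and of nlp2, a knock-out of the NIN-like protein gene NLP2, which encodes a transcription factor of the RWP-RK family. The series addresses the primary nitrate response, the early change in transcripts when nitrate reaches starved plants, and asks how the mutant and the wild type respond. Both genotypes were sampled before starvation, after 3 days of nitrogen starvation and after 3 mM nitrate was supplied, with 3 libraries in each of the 6 groups and 14684639 to 25545031 counted reads per library. The first 2 principal components held 47.2% and 20.8% of the variance. All values given as CPM are means ± SD of 3 libraries, and all adjusted p-values for single genes come from edgeR.

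NLP2 (AT4G35270, chromosome 4, 16777264 to 16782054 on the reverse strand) was lower in nlp2 in all 3 conditions, and the highest nlp2 library lay below the lowest wild-type library in each. Before starvation its level was 26.0 ± 2.7 CPM in wild type and 7.2 ± 3.1 CPM in nlp2, which is 27.6% of wild type. After starvation the levels were 60.3 ± 3.7 and 11.9 ± 2.6 CPM, or 19.7%, and after nitrate 46.1 ± 4.7 and 12.9 ± 4.2 CPM, or 28.0%. The log2 fold changes were -1.85 ± 0.27 (adjusted p = 0.00322), -2.34 ± 0.26 (adjusted p = 0.000178) and -1.82 ± 0.26 (adjusted p = 0.0016). The first of these was not called when only the 6 untreated libraries were fitted (-1.855, adjusted p = 0.0709), while the 12 alternatives together gave -2.068 to -1.55. The counts do not show which part of the transcript the remaining reads came from. No other NLP gene was called by genotype. The value farthest from 0 was that of NLP3 before starvation (-0.76 ± 0.21, adjusted p = 0.217), and NLP7, a main regulator of the nitrate response, was at -0.17, -0.06 and -0.03. The 5 tested genes within 3 models of NLP2 had 15 values between -0.42 and 0.41, and 0 were called (smallest adjusted p = 0.555).

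**Figure D1:**
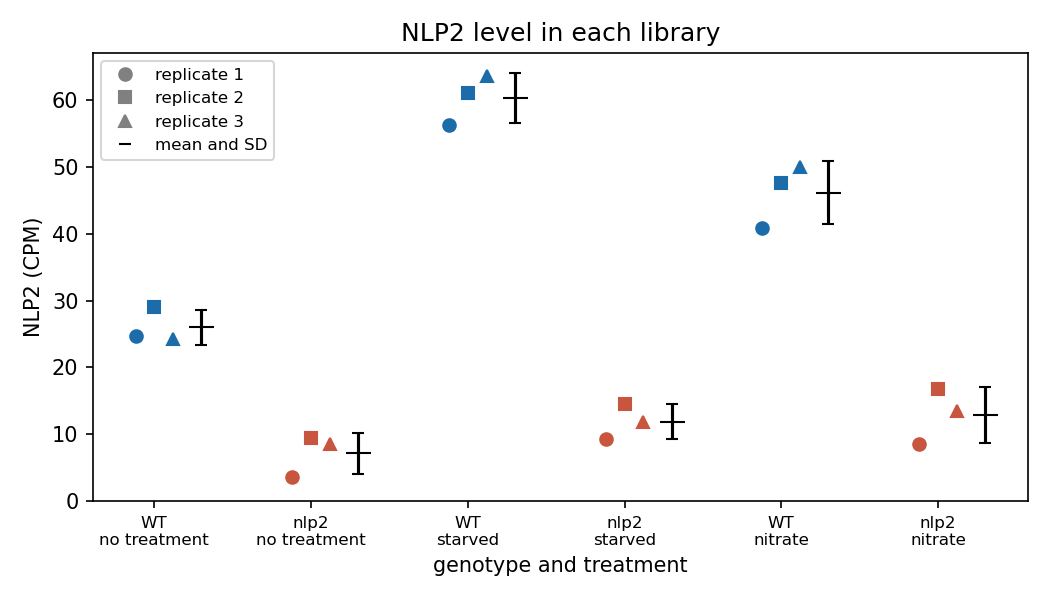
NLP2 transcript level in CPM (vertical axis) in the 6 groups (horizontal axis), with 1 point per library and a bar at the mean with its SD. In each condition all nlp2 libraries lie below all wild-type libraries.

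Starvation against no treatment was compared in each genotype. The nitrate transporter gene NRT2.5, typical of starved plants, went from 0.942 ± 0.0362 to 54.5 ± 9.02 CPM in wild type (log2 fold change 5.85 ± 0.23, adjusted p = 1.04e-11) and from 0.593 ± 0.135 to 64.7 ± 5.47 CPM in nlp2 (6.73 ± 0.23, adjusted p = 3.76e-12). NRT2.4, another such transporter, rose by 3.01 and 3.03, and the urea transporter DUR3 by 2.38 and 2.52. The ammonium transporter AMT1.5 rose by 6.38 ± 0.39 in wild type, and in nlp2 469 reads stood against 3, a ratio of 165 with a 95% counting interval of 56.1 to 803. The list of ammonium, urea and amino acid transport rose in both genotypes, with 11 of 15 members higher and 1 lower in wild type (11 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 8.73e-11, and 0.000274 with an estimated correlation). In nlp2 12 were higher and 1 lower (12 and 1 adjusted over the list alone, median 0.93, adjusted p = 8.76e-15, and 4.3e-05 with an estimated correlation). The nitrate transport list was also higher, with 6 of 21 members higher and 4 lower in wild type (7 and 4 adjusted over the list alone, adjusted p = 0.00487, and 0.0456 with an estimated correlation). In nlp2 12 were higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 0.000162, and 0.00479 with an estimated correlation). The wild-type call with an estimated correlation was lost without untreated wild-type replicate 1, 2 or 3 (adjusted p up to 0.111).

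Regulators of the nitrate response fell under starvation. BT2, which encodes a BTB and TAZ domain protein, changed by -4.99 in wild type and -5.59 in nlp2. The repressor gene HRS1 changed by -3.31 and -4.41, and LBD38, a LOB domain repressor of nitrogen-responsive genes, by -1.91 and -2.05. Of the 20 regulators, 11 were lower and 1 higher in wild type (12 and 1 adjusted over the list alone, median -0.97, camera adjusted p = 2.03e-17, and 0.00531 with an estimated correlation). The same numbers held in nlp2 (11 lower and 3 higher adjusted over the list alone, median -1.04, adjusted p = 2.96e-19, and 0.00479 with an estimated correlation). The NLP family moved the other way, with 7 of 9 members higher in wild type (7 adjusted over the list alone, median 1.22, adjusted p = 9.28e-11, and 0.00531 with an estimated correlation). In nlp2 6 were higher (7 adjusted over the list alone, median 1.28, adjusted p = 2.06e-12, and 0.00278 with an estimated correlation). NLP3 rose by 3.05 ± 0.16 and 3.72 ± 0.17, NLP8 by 2.36 and 2.55 and NLP9 by 1.92 and 1.72, while NLP7 was at -0.03 and 0.07 and NLP6 at -0.07 and -0.06. NLP2 itself rose in wild type (1.22 ± 0.25, adjusted p = 0.00125) and was at 0.73 ± 0.28 in nlp2 (adjusted p = 0.0582). Assimilation genes went both ways. The cytosolic glutamine synthetase genes GLN1.4 (3.17 and 4.06) and GLN1.1 (1.53 and 1.72) rose, while the plastid glutamine synthetase gene GLN2 (-1.13 and -1.18) and the nitrite reductase gene NIR1 (-1.67 and -1.90) fell. This list was not called (5 of 16 members higher and 9 lower in wild type, both counts also adjusted over the list alone, adjusted p = 0.662).

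Among lists on other processes, photosynthesis genes were lower after starvation in 24 of 25 cases in wild type (24 adjusted over the list alone, median -0.97, camera adjusted p = 1.99e-20) and in 24 in nlp2 (25 adjusted over the list alone, median -1.10, adjusted p = 6.7e-25). The small-subunit Rubisco genes RBCS1B (-1.50 and -1.70) and RBCS1A (-1.41 and -1.38) are near-identical copies with uncertain counts. The Calvin cycle gene GAPB changed by -1.09 and -1.16. Flavonoid and anthocyanin genes were higher, 11 of 16 in wild type (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.000136) and 12 with 1 lower in nlp2 (12 and 1 adjusted over the list alone, adjusted p = 1.22e-06). The anthocyanin regulators MYB90 (5.54 and 5.77) and MYB75 (4.29 and 5.84) led the list. Hypoxia genes were higher, 10 of 13 in wild type (11 adjusted over the list alone, adjusted p = 8.04e-05) and 8 in nlp2 (9 adjusted over the list alone, adjusted p = 0.00105), as was the regulator LBD41 (1.55 and 1.41). Cytokinin genes were lower, 10 of 15 with 1 higher in wild type (12 and 1 adjusted over the list alone, adjusted p = 0.0024) and 8 with 1 higher in nlp2 (11 and 1 adjusted over the list alone, adjusted p = 0.00869), with the biosynthesis gene CYP735A1 at -2.25 and -1.98. These calls were lost with an estimated correlation in wild type and nlp2, at an adjusted p of 0.157 and 0.0749 for photosynthesis, 0.157 and 0.0656 for flavonoids, 0.25 and 0.379 for hypoxia and 0.207 and 0.283 for cytokinin.

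Phosphate starvation genes, which include the galactolipid synthase gene MGD3 (2.87 and 3.44), were higher in 7 and lower in 5 of 17 cases in wild type (7 and 5 adjusted over the list alone, adjusted p = 0.0229, and 0.157 with an estimated correlation). In nlp2 they were higher in 6 and lower in 4 cases (6 and 4 adjusted over the list alone, adjusted p = 0.0188, and 0.0833 with an estimated correlation), a call lost without untreated nlp2 replicate 2 (adjusted p = 0.0672). Sulfate assimilation genes were higher in 9 and lower in 1 of 16 cases in wild type (9 and 1 adjusted over the list alone, adjusted p = 0.00467, and 0.393 with an estimated correlation). In nlp2 the list had a median of 0.33 (adjusted p = 0.186). Cytosolic ribosomal protein genes were lower in 11 and higher in 1 of 23 cases in wild type (12 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.0172, and 0.502 with an estimated correlation). In nlp2 12 were lower and 1 higher (14 and 1 adjusted over the list alone, adjusted p = 0.0076, and 0.473 with an estimated correlation), a call lost without untreated nlp2 replicate 1 (adjusted p = 0.0622). In wild type the lists of senescence (median 0.15, adjusted p = 0.912), autophagy (0.13, 0.582), iron (-0.02, 0.316), starch and sugar (-0.01, 0.611), cell cycle (-0.26, 0.145), the circadian clock (-0.31, 0.662) and root tissue markers (0.17, 0.324) were not called. Over all genes 6205 were called in wild type (2948 higher, 3257 lower) and 6441 in nlp2 (3099 higher, 3342 lower). Of these, 2312 were higher and 2739 lower in both genotypes, against 428 and 509.9 for independent lists, and the log2 fold changes correlated at r = 0.901 across genes, which are not independent replicates. Of the 23 lists 11 were called in each genotype, and with an estimated correlation 4 in wild type and 5 in nlp2. Systemic nitrogen demand was called in nlp2 (2 of 3 higher, also adjusted over the list alone, median 0.71, adjusted p = 0.0072, and 0.0461 with an estimated correlation). With an estimated correlation it was lost without untreated nlp2 replicate 1, 2 or 3 or starved nlp2 replicate 1 (adjusted p up to 0.0743). Starved seedlings were also 3 days older than untreated ones.

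Nitrate against starvation was the central comparison. No starved group without nitrate was sampled at the later time. Changes given below as with nitrate can therefore hold effects of handling or elapsed time. Genes that reduce nitrate rose strongly. The nitrite reductase gene NIR1 went from 68.2 ± 10.6 to 4000 ± 167 CPM in wild type (log2 fold change 5.88 ± 0.12, adjusted p = 2.58e-16) and from 52.1 ± 1.87 to 3050 ± 15.4 CPM in nlp2 (5.87 ± 0.13, adjusted p = 2.65e-16). The nitrate reductase gene NIA1 rose by 4.14 in wild type and 3.83 in nlp2 and its paralog NIA2 by 2.26 and 2.22. Of the 16 assimilation genes, 9 were higher and 3 lower in each genotype, also adjusted over the list alone (median 0.73 in both, camera adjusted p = 6.2e-33 in wild type and 3.21e-37 in nlp2, and 2.59e-05 and 1.46e-05 with an estimated correlation). Nitrate transport genes were higher in 12 and lower in 5 of 21 cases in each genotype (12 and 5 in wild type and 12 and 6 in nlp2 adjusted over the list alone, medians 1.19 and 0.89, adjusted p = 7.99e-15 and 3.68e-13, and 1.51e-05 and 3.53e-05 with an estimated correlation). They included NRT2.1, the main high-affinity transporter (3.31 ± 0.28 and 2.98 ± 0.27), its partner protein NRT3.1 (3.27 ± 0.12 and 2.63 ± 0.12), NRT2.2 (4.44 and 4.88) and the nitrate transporter and sensor NRT1.1 (1.75 and 1.67). NRT2.1 and NRT2.2 are near-identical neighbours, so their counts are uncertain.

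Regulators rose with nitrate in 17 of 20 cases and fell in 1 in each genotype (17 and 1 in wild type and 17 and 2 in nlp2 adjusted over the list alone, medians 2.04 and 1.96, also with HHO1 at its bound, camera adjusted p = 5.74e-67 and 4.39e-72, and 1.28e-05 and 1.13e-05 with an estimated correlation). BT2 rose by 5.33 and 6.21, HRS1 by 4.22 and 4.70, LBD37 by 3.31 and 3.36, the HRS1 homolog HHO3 by 2.78 and 2.83, and the kinase gene CIPK3 by 2.66 and 2.76. HHO1, another homolog of HRS1, had 395 reads after nitrate against 1 before in wild type, a ratio of 311 with a 95% counting interval of 55.5 to 12300. In nlp2 it was at least 51.7-fold higher than the floor of 3 counts over the group (156 reads against 0). Among the NLP genes, NLP3 rose by 1.98 and 1.81, while NLP9 (-2.24 and -2.02), NLP8 (-1.19 and -1.15) and NLP5 (-0.91 and -0.99) fell. NLP2 was at -0.39 in wild type (adjusted p = 0.298) and 0.13 in nlp2 (adjusted p = 0.804). The NLP list was not called in either genotype (3 of 9 members higher in both and 3 and 4 lower, 3 higher and 4 lower in both adjusted over the list alone, adjusted p = 0.709 and 0.753).

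Genes that supply reducing power rose in 9 of 10 cases in each genotype, also adjusted over the list alone (medians 3.20 in wild type and 2.80 in nlp2, camera adjusted p = 2.22e-122 and 2.25e-119, and 2.14e-08 and 1.31e-08 with an estimated correlation). They included the plastid glucose-6-phosphate dehydrogenase gene G6PD3 (5.72 ± 0.10 and 5.39 ± 0.10), the 6-phosphogluconate dehydrogenase gene PGD3 (3.77 and 3.40), the root ferredoxin-NADP reductase gene RFNR1 (3.67 and 3.32) and the ferredoxin gene FD3 (3.03 and 2.54). Organic acid genes were higher in 12 and lower in 1 of 25 cases in wild type (12 and 2 adjusted over the list alone, median 0.24, adjusted p = 1.98e-08, and 0.0102 with an estimated correlation). In nlp2 11 were higher (12 and 2 adjusted over the list alone, median 0.13, adjusted p = 7.59e-07, and 0.0156 with an estimated correlation). The tonoplast malate transporter gene TDT rose by 1.91 and 1.95. Sulfate assimilation genes were higher in 11 of 16 cases in both, also adjusted over the list alone (medians 1.09 and 1.31, adjusted p = 1.71e-10 and 1.42e-14, and 0.0385 and 0.0139 with an estimated correlation). The APS reductase gene APR2 was at 2.04 and 2.11. The wild-type sulfate call with an estimated correlation was lost without wild-type replicate 3 after nitrate (adjusted p = 0.0512). Ammonium transporter genes fell, AMT1.1 at -1.15 and -1.03 and AMT1.3 at -1.33 and -1.62. Their list was lower in 5 and higher in 2 of 15 cases in wild type (6 and 2 adjusted over the list alone, adjusted p = 0.0154, and 0.0412 with an estimated correlation). In nlp2 6 were lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.000969, and 0.0139 with an estimated correlation). The wild-type call with an estimated correlation was lost without replicate 1, 2 or 3 of wild type after nitrate (adjusted p up to 0.062).

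**Figure D2:**
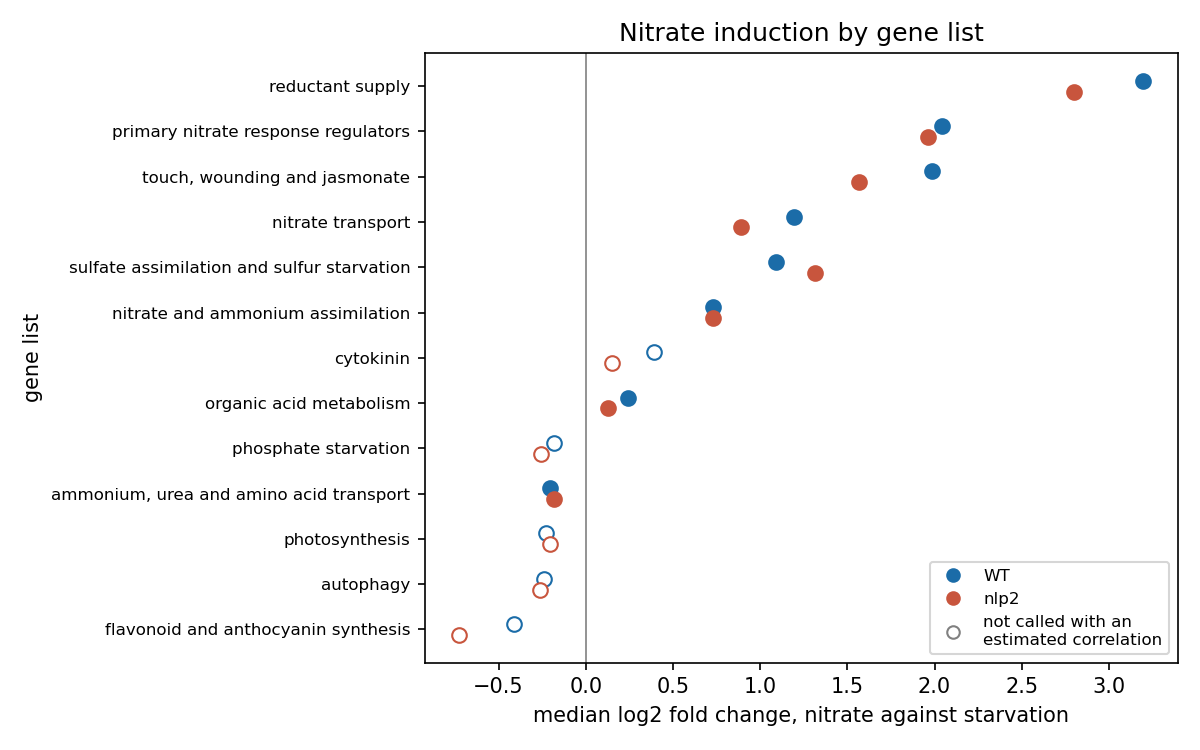
Median log2 fold change of nitrate against starvation (horizontal axis) of gene lists (vertical axis) in wild type and nlp2, with open symbols where the list was not called with an estimated correlation. Reductant supply has medians of 3.20 in wild type and 2.80 in nlp2.

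Touch, wounding and jasmonate genes also rose with nitrate, 16 of 18 in wild type (16 higher and 1 lower adjusted over the list alone, median 1.98, camera adjusted p = 3.23e-19, and 0.0102 with an estimated correlation). In nlp2 13 were higher and 1 lower (13 and 1 adjusted over the list alone, median 1.57, adjusted p = 1.39e-14, and 0.0212 with an estimated correlation). The calmodulin-like gene TCH3 rose by 2.69 and 2.24, the jasmonate repressor gene JAZ10 by 3.50 and 3.38 and the jasmonate catabolism gene CYP94B3 by 3.30 and 2.71. Handling at the supply of nitrate cannot be told apart from nitrate itself for this list. Cytokinin genes were higher in 6 and lower in 3 of 15 cases in wild type (7 and 4 adjusted over the list alone, adjusted p = 0.00128, and 0.162 with an estimated correlation). In nlp2 5 were higher and 1 lower (6 and 3 adjusted over the list alone, adjusted p = 0.00502, and 0.207 with an estimated correlation). Among them were the biosynthesis genes IPT3 (2.28 and 2.00) and CYP735A2 (1.93 and 1.68). Flavonoid genes were lower in 5 of 16 cases in wild type (6 adjusted over the list alone, adjusted p = 0.012, and 0.377 with an estimated correlation). In nlp2 8 were lower (11 adjusted over the list alone, adjusted p = 4.69e-05, and 0.114 with an estimated correlation), with the anthocyanin regulator MYB90 at -2.29 in nlp2. Photosynthesis genes were lower in 4 and 3 of 25 cases, also adjusted over the list alone (adjusted p = 0.00602 and 0.00471, and 0.771 and 0.82 with an estimated correlation). Autophagy genes were lower as a list in wild type (2 of 13 called, also adjusted over the list alone, adjusted p = 0.0456, and 0.697 with an estimated correlation). This was lost without starved wild-type replicate 1 or wild-type replicate 2 or 3 after nitrate (adjusted p up to 0.144). In nlp2 autophagy genes were lower too (1 of 13 called, also adjusted over the list alone, median -0.26, adjusted p = 0.0228, and 0.607 with an estimated correlation). Phosphate starvation genes were called lower in nlp2 (5 lower and 1 higher of 17, and 7 and 1 adjusted over the list alone, median -0.26, adjusted p = 0.0417, and 0.152 with an estimated correlation), but not in wild type (4 lower and 1 higher, median -0.18, adjusted p = 0.206). Both calls in nlp2 were lost without starved nlp2 replicate 1 or nlp2 replicate 2 after nitrate (adjusted p up to 0.0713 and 0.0816). The lists of senescence (median -0.05 in wild type, adjusted p = 0.984), hypoxia (-0.17, 0.805) and the circadian clock (0.13, 0.604) were not called. The hemoglobin gene HB1 rose by 2.00 and 2.37 and the clock gene TOC1 by 0.58 and 0.79.

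Over all genes, nitrate changed 4558 in wild type (2387 higher, 2171 lower, 892 and 319 of them at least 2-fold) and 3969 in nlp2 (1998 higher, 1971 lower; 722 and 290 at least 2-fold). Of these, 1778 were higher and 1601 lower in both genotypes, against 223.4 and 200.5 for independent lists, and 1 gene went opposite ways. The log2 fold changes of the genotypes correlated at r = 0.899 across genes. Of the 23 lists 12 were called in wild type and 13 in nlp2, and 8 in each with an estimated correlation.

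Heat-shock genes stood apart in replicate 1 after nitrate in both genotypes, a list of 18 genes chosen after the data were seen, of which 17 were tested. The median level of the list was 727, 41.3 and 129 CPM in wild-type replicates 1, 2 and 3 after nitrate and 525, 30.4 and 56.7 CPM in nlp2, against 30.9 to 48.6 CPM in starved and 12.3 to 36.1 CPM in untreated libraries. HSP70 reached 8680 CPM in wild-type replicate 1 and 7270 CPM in nlp2 replicate 1. The list took 2.54% and 2.06% of the reads of these 2 libraries and at most 0.67% of any other library after nitrate. Of the 17 genes, 5 were called higher with nitrate in wild type and 3 in nlp2, with the transcription factor gene HSFA2 at 4.28 and 3.92 (camera adjusted p = 0.0422 and 0.115, and 0.931 in both with an estimated correlation). Without these 2 libraries nitrate changed 3733 genes in wild type (2065 higher, 1668 lower, 3497 shared with the full set) and 3547 in nlp2 (1995 higher, 1552 lower, 3199 shared). The members called without them were 12 higher and 4 lower for nitrate transport, 9 and 1 for assimilation, 17 and 0 for regulators and 9 and 0 for reductant supply in each genotype. The wild-type calls with an estimated correlation were lost for ammonium and amino acid transport (adjusted p = 0.0838) and sulfate assimilation (adjusted p = 0.0509).

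**Figure D3:**
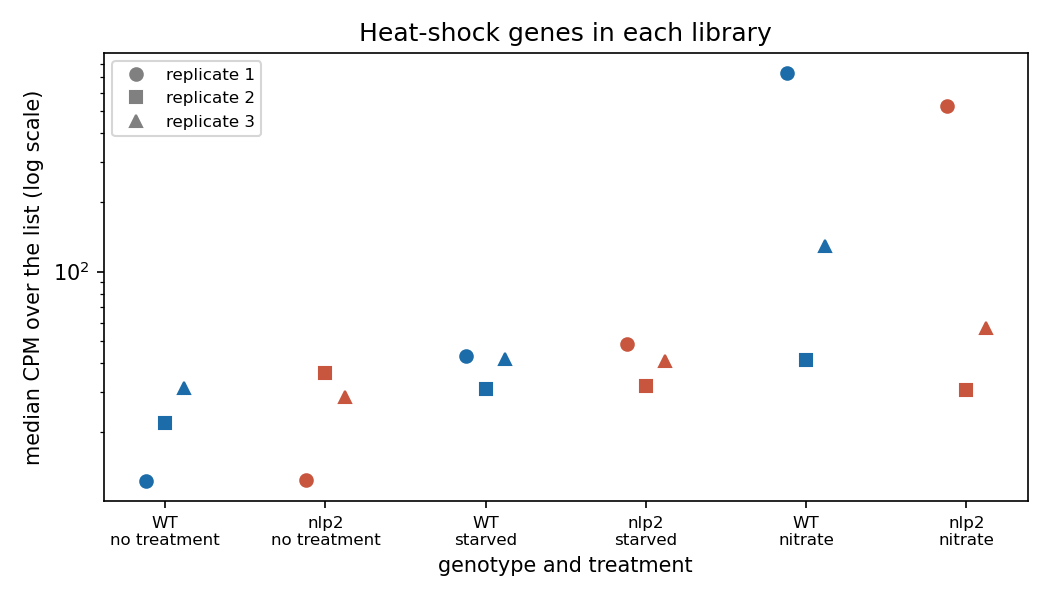
Level of heat-shock genes in CPM (vertical axis, log scale) in each library of the 6 groups (horizontal axis), as the median of the 17 tested genes. Replicate 1 after nitrate reached 727 CPM in wild type and 525 CPM in nlp2.

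Before starvation, 77 genes differed between nlp2 and wild type, 58 higher and 19 lower in nlp2. MRD1 (AT1G53480, chromosome 1, 19963047 to 19964712) was at 0.65 ± 0.177 CPM in wild type and 40 ± 6.4 CPM in nlp2 (log2 fold change 5.92 ± 0.23, adjusted p = 1.65e-11). The gene HEI10 (AT1G53490, 19963267 to 19966952), which acts in meiotic crossing over, overlaps MRD1 on the other strand and was 1.79 ± 0.23 higher (adjusted p = 0.000513), so the reads of the pair are uncertain. CAX3, a vacuolar proton and calcium exchanger, was 2.09 ± 0.18 higher (adjusted p = 6.8e-06) and the nitrilase gene NIT2 1.66 ± 0.24 higher (adjusted p = 0.00259). Lower in nlp2 were FUM2, the cytosolic fumarase gene (-1.58 ± 0.21, adjusted p = 0.000788), the transporter gene UMAMIT36 (-2.44 ± 0.30, adjusted p = 0.000371), the zinc pump gene HMA2 (-1.50 ± 0.24, adjusted p = 0.00561) and the nicotianamine synthase gene NAS1 (-0.74 ± 0.11, adjusted p = 0.00261). The list of systemic nitrogen demand, of 3 genes, was lower (0 higher and 1 lower, and 0 and 2 adjusted over the list alone, median -0.82, camera adjusted p = 3.8e-07, and 0.00227 with an estimated correlation). Its member CEPD2, a glutaredoxin that signals nitrogen demand from shoot to root, was at -1.07 ± 0.19 (adjusted p = 0.0119). Nitrate transport genes were lower as a list (1 of 21 called lower, and 4 lower with 1 higher adjusted over the list alone, median -0.24, adjusted p = 0.00177, and 0.0378 with an estimated correlation). Its called member was NRT1.1 (-0.62 ± 0.11, adjusted p = 0.00867). NRT1.1 and CEPD2 were not called without wild-type replicate 1 (-0.51 and -0.96, both at an adjusted p of 0.0784) or nlp2 replicate 2, and the transport list was not called without nlp2 replicate 1 or 2 (adjusted p up to 0.0595). With an estimated correlation the transport list was also lost without wild-type replicate 1 or 2 (adjusted p up to 0.325 over the 4 libraries).

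With the replicate number as a block, 143 genes differed before starvation (92 higher, 51 lower in nlp2), and with the 6 libraries fitted alone 17 genes did, which did not include FUM2, UMAMIT36, HMA2, NAS1, NRT1.1 or CEPD2. The count was 39 without untreated wild-type replicate 1, 35 without wild-type replicate 2 and 46 without nlp2 replicate 3. Calls were made for 8 of 23 lists, and for 2 with an estimated correlation. The NLP family, which holds NLP2 itself, was called lower (1 of 9 called, and 2 adjusted over the list alone, median -0.10, adjusted p = 0.00177, and 0.155 with an estimated correlation). The call was lost without nlp2 replicate 1 (adjusted p = 0.134). It was also lost once NLP2 was left out of the list (0 of 8 called, and 1 adjusted over the list alone, adjusted p = 0.229, and 0.568 with an estimated correlation), so that it restates the knock-out. Photosynthesis genes were lower (0 of 25 called, also adjusted over the list alone, median -0.20, adjusted p = 3.77e-06, and 0.568 with an estimated correlation), but not without nlp2 replicate 2 (adjusted p = 0.346). Touch, wounding and jasmonate genes were higher (0 of 18 called, and 3 adjusted over the list alone, median 0.38, adjusted p = 1.28e-05, and 0.316 with an estimated correlation), but not without wild-type replicate 1 (adjusted p = 0.0777). Iron, starch and sugar, and hypoxia were called lower at an adjusted p of 0.029, 0.029 and 0.0156, and at 0.155, 0.422 and 0.568 with an estimated correlation. Of their members 0 of 11, 0 of 12 and 0 of 13 were called, also adjusted over the list alone. The iron call was lost without wild-type replicate 1 or 2 or nlp2 replicate 1 or 3 (adjusted p up to 0.299), the starch call without wild-type replicate 3 or nlp2 replicate 1 or 2 (up to 0.401), and the hypoxia call without wild-type replicate 1 or nlp2 replicate 1 or 2 (up to 0.258). Only 3 lists were called without nlp2 replicate 1 and 4 without nlp2 replicate 2.

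After starvation, 78 genes differed, 60 higher and 18 lower in nlp2. MRD1 was again far higher (0.683 ± 0.337 against 38.9 ± 1.9 CPM, 5.84 ± 0.23, adjusted p = 2.1e-11), with HEI10 at 2.74 ± 0.25 (adjusted p = 5.67e-06). BGL2, a beta-1,3-glucanase gene of the defence response, was at 1.46 ± 0.911 CPM in wild type and 23.3 ± 6.72 CPM in nlp2 (4.02 ± 0.44, adjusted p = 0.000173). The calmodulin-like gene CML41 was 3.27 ± 0.24 higher (adjusted p = 3.11e-07), the receptor-like protein gene RLP38 3.12 ± 0.31 higher (adjusted p = 1.89e-05) and CAX3 2.27 ± 0.17 higher (adjusted p = 5.66e-07). FUM2 was lower (18.4 ± 2.17 against 7.25 ± 0.815 CPM, -1.34 ± 0.20, adjusted p = 0.00319). Photosynthesis genes were lower as a list although 0 of 25 were called, also adjusted over the list alone (median -0.36, camera adjusted p = 3.7e-16, and 0.378 with an estimated correlation). The same held for hypoxia genes with 0 of 13 called, also adjusted over the list alone (median -0.39, adjusted p = 2.54e-05, and 0.378 with an estimated correlation). Sulfate assimilation genes were lower (1 of 16 called, also adjusted over the list alone, median -0.20, adjusted p = 7.85e-05, and 0.378 with an estimated correlation). Ammonium, urea and amino acid transport genes were higher (1 of 15 called, also adjusted over the list alone, median 0.15, adjusted p = 0.00294, and 0.0706 with an estimated correlation). The touch, wounding and jasmonate list was higher (1 of 18 called, also adjusted over the list alone, adjusted p = 0.00925, and 0.64 with an estimated correlation), but not without wild-type replicate 2 or 3 or nlp2 replicate 1 (adjusted p up to 0.212). The regulator list was lower at an adjusted p of 0.0493 (0 of 20 called, also adjusted over the list alone, and 0.64 with an estimated correlation) and was lost in 5 refits, all but that without wild-type replicate 1 (up to 0.424). With the replicate block it was also lost (0.051), and the flavonoid list was added (adjusted p = 0.0484). The NLP family was added too (0.0464), but not once NLP2 was left out of it (0.729). Calls were made for 6 lists, and for 0 with an estimated correlation. The blocked fit called 137 genes (84 higher, 53 lower). Without starved wild-type replicate 1, 2 or 3 or nlp2 replicate 1 or 2, 37, 39, 42, 50 and 45 genes were called.

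After nitrate, 168 genes differed, 78 higher and 90 lower in nlp2. MRD1 (5.11 ± 0.20, adjusted p = 2.97e-11), BGL2 (3.84 ± 0.42, adjusted p = 0.000139), RLP38 (3.11 ± 0.27, adjusted p = 5.25e-06) and HEI10 (2.56 ± 0.23, adjusted p = 5.5e-06) were again higher. So were the cysteine-rich receptor kinase genes CRK7 (3.52 ± 0.32, adjusted p = 5.25e-06) and CRK6 (2.84 ± 0.20, adjusted p = 2.05e-07). FUM2 was lower (63.1 ± 7.2 against 19.4 ± 3.87 CPM, -1.69 ± 0.19, adjusted p = 6.55e-05). NRT2.1 was at -0.10 (adjusted p = 1), NIA1 at 0.02 (adjusted p = 1) and NIR1 at -0.39 (adjusted p = 0.0917). Reductant supply genes were lower in nlp2, 5 of 10 over all genes and 9 adjusted over the list alone (median -0.37, camera adjusted p = 6.88e-12, and 0.00509 with an estimated correlation). G6PD3 was at 610 ± 28.2 CPM in wild type and 456 ± 23.4 CPM in nlp2 (-0.42 ± 0.08, adjusted p = 0.0171), and PGD1 at 443 ± 14.9 and 339 ± 12.1 CPM (-0.39 ± 0.07, adjusted p = 0.00994). G6PD3 was lost without wild-type replicate 3 (-0.39, adjusted p = 0.113), nlp2 replicate 1 or nlp2 replicate 3, and PGD1 without wild-type replicate 3 (-0.36, adjusted p = 0.0682) or nlp2 replicate 2. The number of the 10 genes called was 0 without wild-type replicate 3, 1 without nlp2 replicate 2 or 3 and 2 without wild-type replicate 1, while the list stayed called in every such refit with an estimated correlation (adjusted p up to 0.0228).

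Nitrate transport genes were lower in nlp2 after nitrate as a list (1 of 21 called, and 4 adjusted over the list alone, median -0.14, camera adjusted p = 0.00107, and 0.0281 with an estimated correlation). The call with an estimated correlation was lost without wild-type replicate 2 or 3 or nlp2 replicate 1 or 2 (adjusted p up to 0.271). Its called member NRT2.2 (-0.83 ± 0.16, adjusted p = 0.0163), an uncertain near-identical copy, was lost without wild-type replicate 1 or 3 or nlp2 replicate 2 or 3 (adjusted p up to 0.0985). Regulators were lower (1 of 20 called, and 4 adjusted over the list alone, median -0.14, adjusted p = 0.00011, and 0.336 with an estimated correlation). Photosynthesis genes were also lower (0 of 25 called, also adjusted over the list alone, median -0.35, adjusted p = 3.05e-12, and 0.336 with an estimated correlation). The organic acid list was called lower (3 of 25 called, and 4 adjusted over the list alone, adjusted p = 0.00693, and 0.336 with an estimated correlation, lost without wild-type replicate 1, adjusted p = 0.225). Its median was -0.034 and its mean -0.152, with 13 members below 0 and 12 above. The call therefore does not describe a fall of the list as a whole. Hypoxia (0 of 13 called, also adjusted over the list alone, adjusted p = 0.00169, and 0.439 with an estimated correlation) was lost without wild-type replicate 1 (0.166). Touch, wounding and jasmonate (0 of 18 called, and 1 lower adjusted over the list alone, 0.0416, and 0.598 with an estimated correlation) was lost without wild-type replicate 2 or 3 or nlp2 replicate 1 or 2 (up to 0.496). In all 7 lists were called, and 2 with an estimated correlation, nitrate transport and reductant supply. With the replicate block 360 genes differed (147 higher, 213 lower). The count was 83 without wild-type replicate 3, 81 without nlp2 replicate 2 and 97 without nlp2 replicate 3. Without the 2 replicate 1 libraries rich in heat-shock transcripts 162 genes differed (116 higher, 46 lower, 98 shared with the full set), and 13 of the 29 named genes called were lost. Among these were the reductant supply genes G6PD3, PGD1, PGD3 and TRA2. The reductant list kept a median of -0.32, with 0 of 10 members called by edgeR and an adjusted p of 0.0694 with an estimated correlation. Nitrate transport had a median of -0.079 with 0 of 21 members called (camera adjusted p = 0.01, and 0.297 with an estimated correlation), while organic acids and touch were lost (camera adjusted p = 0.218 for both). The heat-shock list itself had a median of -0.58 in nlp2 against wild type after nitrate (0 of 17 called, limma camera, adjusted p = 0.124, and 0.931 with an estimated correlation).

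**Figure D4:**
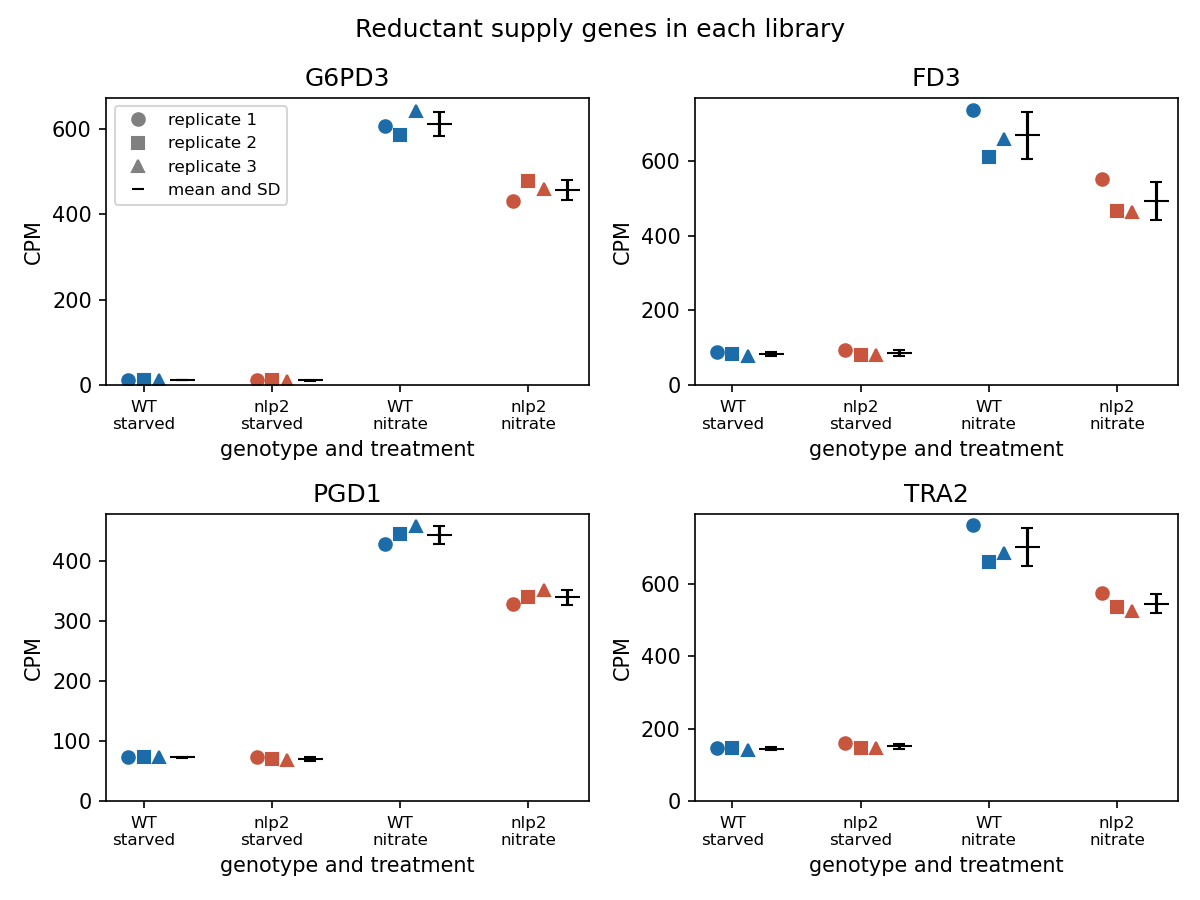
Level of reductant supply genes in CPM (vertical axis) in each library of wild type and nlp2 after starvation and after nitrate (horizontal axis), for G6PD3, FD3, PGD1 and TRA2. After nitrate G6PD3 averaged 610 CPM in wild type and 456 CPM in nlp2.

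Besides NLP2, 27 genes differed in the same direction in all 3 conditions, 23 higher and 4 lower in nlp2. AT3G18535, annotated as a tubulin-tyrosine ligase, had 2 reads over the 9 wild-type libraries and 2246 over the 9 nlp2 libraries (164 to 365 each). It was at least 186-fold higher in nlp2 before starvation and at least 214-fold higher after starvation, against the floor of 3 counts over the group, and after nitrate the ratio was 536 with a 95% counting interval of 148 to 4440. AT1G33930, a P-loop nucleoside triphosphate hydrolase gene, went the other way, with 174 reads in wild type and 6 in nlp2, a ratio of 29.3 with an interval of 13.2 to 81. The others with the largest mean change were MRD1, BGL2, the aspartyl protease gene AT5G10760, RLP38, CML41, the natriuretic peptide gene PNP-A, HEI10 and AT5G35935, all higher in nlp2. Before starvation the calls of BGL2 (2.75, adjusted p = 0.0317), RLP38 (1.88, adjusted p = 0.0123) and PNP-A (2.12, adjusted p = 0.0342) were weak. BGL2 was lost without wild-type replicate 1, 2 or 3 or nlp2 replicate 2 or 3 (adjusted p up to 0.195). RLP38 was lost without wild-type replicate 1 or 2 or nlp2 replicate 3 (up to 0.0784), and PNP-A without any of the 6 libraries (up to 0.178). Pairs of conditions shared 29 higher and 6 lower genes (before and after starvation), 28 and 9 (before starvation and after nitrate) and 45 and 12 (after starvation and after nitrate), against at most 0.2 for independent lists.

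The genes called by genotype in any condition were not concentrated around NLP2. Of 221 such genes on the nuclear chromosomes, 18 lay within 5 Mb of NLP2, or 8.14%, against 7.6% of all tested genes (odds ratio 1.08, Fisher's exact test, two-sided, p = 0.702). Among windows along the chromosomes the highest share was 6 of 186 genes, or 3.23%, on chromosome 1 from 12 to 16 Mb. ADR1, AT1G33930 and NAC016, chosen here after their positions were seen, lie there and differed in each condition. Whether this window holds more called genes than others was not tested.

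The difference between the genotypes in the nitrate response was tested directly. Reductant supply genes rose less in nlp2. The list had a median difference of -0.34, all 10 members lay below 0, and 0 were called over all genes but 6 adjusted over the list alone (camera adjusted p = 2.88e-15, and 0.00142 with an estimated correlation). The differences were -0.49 ± 0.14 for FD3, -0.42 ± 0.11 for the transaldolase gene TRA2, -0.37 ± 0.11 for PGD3, -0.33 ± 0.10 for PGD1 and -0.33 ± 0.13 for G6PD3, each at an adjusted p of 1 over all genes. Adjusted over the list alone, p was 0.00995 for the first 4 of these and 0.0304 for G6PD3. The list stayed called in each of the 12 refits without 1 library (adjusted p up to 0.0095 with an estimated correlation). When the genotype labels were regrouped at random within each treatment, 5 of 100 groupings, the real one included, gave a list median as far from 0. This share is no chance rate, since some groupings leave the genotypes apart after nitrate. Among the 32 groupings that part the replicate pairs, all those as far from 0 did so. The list also stayed called without the 2 replicate 1 libraries after nitrate (median -0.30, adjusted p = 0.0169 with an estimated correlation). Touch, wounding and jasmonate genes also had a smaller response in nlp2 (0 of 18 called, also adjusted over the list alone, median -0.50, adjusted p = 2.79e-09, and 0.167 with an estimated correlation). Heat-shock genes moved the same way (0 of 17 called, median -0.77, camera adjusted p = 0.0422, and 0.931 with an estimated correlation). Without the 2 libraries the touch list had a median of -0.28 (adjusted p = 6.43e-07, and 0.261 with an estimated correlation).

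Over single genes the difference in the nitrate response gave 0 calls with edgeR (smallest adjusted p = 0.0613, 313 genes at an unadjusted p below 0.05, against 1067 expected by chance), 0 with the replicate block and 2 with DESeq2. Those 2, chosen after their values were seen, were AT3G44800 (-2.44, adjusted p = 0.00798 with DESeq2 and 0.0613 with edgeR) and AT4G32950 (-1.03, adjusted p = 0.000732 and 0.354). The 313 genes are fewer than the 1067 expected without any difference, so the edgeR test was conservative here. Its 0 calls therefore do not show equal responses. The transporter partner NRT3.1 had a difference of -0.64 and CLCB, another member of the nitrate transport list, of -0.44, each at an adjusted p of 1. Of the lists 5 were called, 1 with an estimated correlation, and 3 without starved wild-type replicate 1. Nitrate transport (adjusted p = 0.0142), organic acid metabolism (0.01) and flavonoid synthesis (0.0035) were also called as lists, at 0.122, 0.337 and 0.351 with an estimated correlation. Of their members 0 of 21, 0 of 25 and 0 of 16 were called, and 2, 1 and 0, all lower, adjusted over the list alone. Transport was lost without wild-type replicate 1 or 3 after starvation, wild-type replicate 3 after nitrate, or nlp2 replicate 1 or 2 after nitrate (adjusted p up to 0.117). Organic acids were lost without starved wild-type replicate 1, wild-type replicate 1 after nitrate or nlp2 replicate 2 after nitrate (up to 0.232), and flavonoids without wild-type replicate 1 after nitrate, starved nlp2 replicate 1 or nlp2 replicate 2 after nitrate (up to 0.108). Without the 2 replicate 1 libraries after nitrate organic acids were lost (median 0.007, adjusted p = 0.178). Transport (median -0.018) and flavonoids (median -0.193) were each at 0.0461, and at 0.261 and 0.714 with an estimated correlation. Sulfate assimilation was then called with a larger response in nlp2 (median 0.246, adjusted p = 5.8e-07, and 0.261 with an estimated correlation). Over the 3518 genes that rose with nitrate the median difference was -0.06 (medians 0.56 in wild type and 0.49 in nlp2), and the rise was smaller in nlp2 for 68.2% (camera adjusted p = 4.56e-06, and 0.0199 with an estimated correlation). Without the 2 replicate 1 libraries after nitrate it was -0.02. Over the 3645 genes that fell it was 0.01 (adjusted p = 0.0255, and 0.288 with an estimated correlation). When the genotype labels were regrouped at random within each treatment, 11 of 100 groupings, the real one included, gave a median as far from 0 for the genes that rose and 83 for those that fell. As for the reductant list, these shares are no chance rate, since some groupings leave the genotypes apart after nitrate.

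The difference between the genotypes in the starvation response also gave 0 calls with edgeR (smallest adjusted p = 0.126, 395 genes at an unadjusted p below 0.05, against 1067 expected by chance), 1 with the replicate block and 2 with DESeq2. The edgeR test was conservative here too, so its 0 calls do not show equal responses. NF-YA2, a subunit of a CCAAT-binding transcription factor chosen after its values were seen, had a difference of -0.63 (adjusted p = 0.012 with the block, 6.5e-08 with DESeq2 and 0.126 with edgeR). The other DESeq2 call, chosen likewise, was AT5G37990 (-0.92, adjusted p = 0.025, against 1 with edgeR). The systemic nitrogen demand list rose more in nlp2 (0 of 3 called, and 1 adjusted over the list alone, median 0.71, camera adjusted p = 1.33e-06, and 0.00323 with an estimated correlation). Its member CEPD2, chosen after its values were seen, rose by 1.04 ± 0.18 in wild type and 2.19 ± 0.19 in nlp2, a difference of 1.15 at an adjusted p of 1. The list was called in each of the 12 refits without 1 library (adjusted p up to 0.0337 with an estimated correlation). Systemic demand genes were already lower in nlp2 before starvation (median -0.825, 3 of 3 members below 0). The difference uses the same untreated libraries, so it is not a finding independent of that one. Nitrate transport rose slightly more in nlp2 as a list, with a median of 0.048 and 15 members above 0 against 6 below (0 of 21 called, and 3 higher adjusted over the list alone, adjusted p = 0.0033, and 0.0348 with an estimated correlation). So did ammonium, urea and amino acid transport (0 of 15 called, and 1 higher adjusted over the list alone, adjusted p = 0.0024, and 0.031 with an estimated correlation). Nitrate transport genes too were lower in nlp2 before starvation (median -0.236), in the same untreated libraries. In total 7 lists were called, 3 with an estimated correlation, and only 2 without untreated nlp2 replicate 1. Transport of nitrate was lost without untreated nlp2 replicate 1 or 2 (adjusted p up to 0.054) and transport of ammonium and amino acids without untreated nlp2 replicate 1 (0.0511); with an estimated correlation each was lost in 8 of the 12 refits. Sulfate assimilation genes rose less in nlp2 (0 of 16 called, and 1 lower adjusted over the list alone, median -0.22, adjusted p = 7.42e-05, and 0.271 with an estimated correlation). The other 3 lists called were starch and sugar (0 of 12 members called, adjusted p = 0.00167), photosynthesis (0 of 25, 0.0039) and flavonoids (0 of 16, 0.00685), with 0 members of each also adjusted over the list alone. With an estimated correlation these 3 were at 0.169, 0.834 and 0.441.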

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

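The tests of a shared day, of the nitrate response itself, of a segment linked to NLP2, of a difference unlinked to NLP2 and of scaling, and the splits for the differences that keep the replicate pairs, were chosen only after the results were seen, as were the heat-shock and salicylic acid lists, the NLP family list without NLP2 and the adjustment of p over their 18 tests.

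Reductant supply genes responded less to nitrate in nlp2, by a median of -0.344, and a test of the difference between the genotypes called the list. The tables argue against the replicate 1 libraries after nitrate as the whole source (-0.301 without them). Thinning every library to the smallest total gave -0.339, but thinning keeps the expected ratios between libraries. It could hardly move the list median, so it is no test of library depth. Scaling between libraries was not put to a test, since the other factors moved nothing (list median minus median of all genes -0.329 with both). Chance is not excluded, but groupings of genotype within treatment do not measure it here. As far from 0 lay 5 of 100, the real one included (highest other -0.421), and 5 of the 32 that part the 3 replicate pairs in each treatment. The 4 others of these last kept or swapped the genotypes in all 3 pairs after nitrate, so they hold that genotype difference in full. Among the 32, the farthest that mixed the genotypes after nitrate gave -0.207. With chance undecided, a smaller reductant response without NLP2 may be kept only as a hypothesis.

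Heat-shock genes were high after nitrate in replicate 1 of both genotypes. A shared day or planting that affected all of replicate 1 is argued against by the untreated and starved groups, where replicate 1 lay at most 0.449 (log2) above the mean of the others. The nitrate response itself stays open, because the gap between replicate 1 and the higher of replicates 2 and 3 (2.061 in wild type and 2.874 in nlp2) restates what singled these genes out, and the list rose over starvation by 3.797, 0.056 and 1.736 in wild-type replicates 1, 2 and 3 and by 3.395, -0.184 and 0.521 in nlp2. Handling of the 2 libraries, such as warmth on the day of sampling, could be a source that was not tested.

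The 27 genes changed in all 3 conditions may follow from the loss of NLP2 or from other differences of the line. A segment linked to NLP2 is argued against, since 0% of them lay within 5 Mb of it. A difference of the line unlinked to NLP2 cannot be told apart from the loss of NLP2, with 1 allele and no complemented line. This holds for all 27 genes and for every other difference by genotype. Among the 27, AT3G18535 and AT1G33930 had a mean below 0.1 CPM in 1 genotype in all 3 conditions. Salicylic acid defence genes, of which 24 of 28 were tested and which leave out the genes seen before, had medians of 0.24, 0.29 and 0.28 in nlp2 against wild type before starvation, after starvation and after nitrate (limma camera with an estimated correlation, p = 0.058, 0.0122 and 0.0111). Adjusted over the 18 tests these were 0.348, 0.11 and 0.11, so a raised defence state is a candidate explanation only.

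Other differences between the genotypes, each found by a test of the difference itself, are given as medians. In the nitrate response they were -0.5 for touch, wounding and jasmonate, -0.267 for flavonoids, -0.02 for organic acids and -0.087 for nitrate transport (camera adjusted p = 0.167, 0.351, 0.337 and 0.122 with an estimated correlation). In the starvation response they were 0.711 for systemic nitrogen demand, -0.216 for sulfate assimilation, 0.146 for starch and sugar, 0.145 for ammonium, urea and amino acid transport, 0.048 for nitrate transport, -0.159 for photosynthesis and 0.156 for flavonoids. Of these last lists, starch, flavonoids and photosynthesis had 0 of 12, 0 of 16 and 0 of 25 members called (camera adjusted p = 0.00167, 0.00685 and 0.0039). Starch was lost without untreated nlp2 replicate 1 (camera adjusted p = 0.0511), flavonoids without untreated wild-type replicate 3, untreated nlp2 replicate 1 or starved nlp2 replicate 1 (up to 0.421), and photosynthesis without untreated wild-type replicate 2, starved wild-type replicate 1 or 3, untreated nlp2 replicate 1 or starved nlp2 replicate 2 (up to 0.881). With an estimated correlation these 3 were at 0.169, 0.441 and 0.834 and sulfate at 0.271, while systemic demand, ammonium and nitrate transport were at 0.00323, 0.031 and 0.0348. Systemic demand, nitrate transport and starch were lower in nlp2 before starvation (medians -0.825, -0.236 and -0.173). Their larger rise rests in part on those same untreated libraries. Over genes that rise with nitrate the median difference was -0.061 and over genes that fall 0.007, and chance is not excluded for either. As far from 0 lay 11 and 83 of 100 groupings, the real one included (highest others 0.0864 and 0.0825), and 5 and 24 of the 32 that keep the pairs. These shares are no chance rate, since some groupings leave the genotypes apart in a treatment.

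For the count of genes in the 2 differences the groupings are no test, since any grouping gives at least the 0 found with edgeR. This was so for 100 of 100 in the nitrate response (highest other 184, DESeq2 2, and 313 at an unadjusted p below 0.05) and for 100 of 100 in the starvation response (highest other 766, DESeq2 2, and 395 at an unadjusted p below 0.05). Chance is not excluded for the lists, with 47 of 100 groupings, the real one included here and below, for the 5 lists of the nitrate response (highest other 10) and 18 of 100 for the 7 lists of the starvation response (highest other 10). Some groupings leave the genotypes apart in a treatment, so these shares are no chance rate. Of the 32 that keep the pairs, 16 gave as many lists for the nitrate response and 6 for the starvation response, and the highest other called 432 and 205 genes. These came from the grouping that swaps all 3 pairs in the second treatment only, which adds up the genotype effects of both treatments. The 184 and 766 genes came from a grouping that sets wild-type replicates 1 and 3 and nlp2 replicate 1 against the rest and swaps the 2 sides in the second treatment.

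Each comparison of 2 groups has 10 splits of its 6 libraries, too few for a share under 0.05. Every split but the real one mixes the 2 groups, so a real difference enters the spread within its groups and can lower its calls. The counts of the other splits, 0 included, are therefore no measure of chance. As many genes as the real split came from 1 split before starvation (77, highest other 72), 1 after starvation (78, highest other 4) and 2 after nitrate (168, highest other 291). The 291 genes came from wild-type replicates 1 and 3 with nlp2 replicate 1 against the rest, which follows replicate number in part, and the 72 genes from the same numbers before starvation. Among the splits that part the 3 replicate pairs as the real one does, the highest other gave 0 genes in each condition, and with the replicate block the real counts were 143, 137 and 360. The numbers of lists were 8 (3 splits, highest other 12), 6 (2 splits, highest other 6) and 7 (3 splits, highest other 9), and among the splits that part the 3 pairs the highest other gave 10, 5 and 8 lists. For nitrate against starvation 1 split gave 4558 genes in wild type and 1 gave 3969 in nlp2 (highest other 0 in both), and 1 each gave 12 and 13 lists (highest other 11 and 10). For starvation against no treatment 1 split each gave 6205 and 6441 genes (highest other 0 in both), 2 gave 11 lists in wild type (highest other 12) and 1 gave 11 lists in nlp2 (highest other 9).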

How the results depend on the processing

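Leaving out the replicate 1 libraries after nitrate of both genotypes was chosen only after the results were seen. Counts of genes by genotype before starvation, after starvation and after nitrate were 157, 152 and 314 with DESeq2, 143, 137 and 360 with the replicate block, 17, 168 and 104 with only the compared groups fitted, and 21, 24 and 32 against a 1.5-fold change. That last test left 1036 and 814 genes for nitrate and 1509 and 1537 for starvation in wild type and nlp2. For the differences of the nitrate and starvation responses edgeR called 0 genes (313 and 395 at an unadjusted p below 0.05), DESeq2 2 and 2, and the block 0 and 1. With an estimated inter-gene correlation 2, 0 and 2 lists were called by genotype, 8 for nitrate in nlp2, 4 and 5 for starvation, and 1 and 3 for the differences. The block changed 3 list calls, all after starvation, and no other list call, and it kept all 432 called values of named genes. Of these values 31 lost their call with only the compared groups fitted, 15 with no filter on low counts, 4 with RLE scaling and 0 with DESeq2. NLP2 before starvation was at -1.855 with only the compared groups fitted (edgeR, adjusted p = 0.0709, the highest of its 12 alternatives). The median over genes that fall with nitrate was 0.009 without the 2 replicate 1 libraries.

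Without 1 library at a time, counts by genotype ranged from 35 to 67 before starvation, 37 to 59 after starvation and 81 to 201 after nitrate. They ranged from 3397 to 3892 and 3040 to 3446 for nitrate, and from 5015 to 5414 and 5255 to 6220 for starvation, in wild type and nlp2, and were 0 for both differences (edgeR). Lists called ranged from 3 to 12, 4 to 6 and 5 to 10 by genotype, 11 to 12 and 11 to 14 for nitrate, 11 to 12 and 10 to 12 for starvation, and 3 to 7 and 2 to 10 for the differences. NLP2 ranged from -2.068 to -1.55, -2.52 to -2.186 and -2.066 to -1.601. The median over genes that rise ranged from -0.082 to -0.039, and over genes that fall from -0.018 to 0.039, with the sign turned without starved wild-type replicate 3 (-0.003), wild-type replicate 1 after nitrate (-0.001), starved nlp2 replicate 2 (-0.018) and nlp2 replicate 3 after nitrate (-0.015). Uncalled values also turned for NIA1 by genotype after nitrate (-0.024 to 0.083) and NLP2 with nitrate in nlp2 (-0.112 to 0.354). The counts at the low ends came without untreated wild-type replicate 2 (35), starved wild-type replicate 1 (37) and nlp2 replicate 2 after nitrate (81). Of 432 called values of named genes none turned sign, but 247 of their 2592 refits lost the call. The cause of these shifts was not tested.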

Other observations

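The salicylic acid list, chosen after the data were seen, also moved with nitrate. WRKY38, a transcription factor gene of the salicylic acid response, rose by 4.25 in wild type and 3.53 in nlp2, WRKY18 by 2.59 and 2.42, the salicylic acid exporter gene EDS5 by 1.19 and 1.33 and PAD4, which acts with EDS1 in defence, by 0.98 in both. Of 24 members 10 were higher in wild type (median 0.35, limma camera, adjusted p = 0.00324, and 0.504 with an estimated correlation). In nlp2 9 were higher and 1 lower (median 0.47, adjusted p = 0.000684, and 0.433 with an estimated correlation). By genotype, CBP60G, a regulator of salicylic acid synthesis, was higher in nlp2 after starvation (1.47, adjusted p = 0.0136) and after nitrate (1.22, adjusted p = 0.0459), as was NUDT6 (1.25, adjusted p = 0.00749, and 1.61, adjusted p = 0.000227). EDS1 was higher after nitrate (0.56, adjusted p = 0.00321), and 0 of the 24 genes were called before starvation.

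Replicate numbers carried a signal across groups. Of 45 pairs of libraries with the same number in different groups, 31 correlated above 0.1 in their deviations from the group means. Over all 45 pairs the correlations ran from -0.07 to 0.554, and in 37 the correlation with the same number was higher than with any other number.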
